A study of Homo sapiens with 4 samples.

How the data were processed

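Total RNA of JEKO-1 and MINO, untreated or after 5-azadC, was reverse transcribed with pools of stem-loop primers, pre-amplified and read by real-time PCR on TaqMan human microRNA arrays, card A version 2.0 and card B version 3.0, per the labels' protocols. The labels name 45 cycles, while the deposited Ct table lists 40 where no amplification was recorded. Per the labels, the authors subtracted the mean Ct of U6, RNU44 and RNU48, and computed relative levels against the untreated sample with the instrument software (SDS version 2.4; RQ manager version 1.2). The authors deposited 3 tables: Ct values, normalized levels as a linear ratio to the controls of the same card, and the ratio (fold change) of treated to untreated cells in each line. Where 1 of the 2 samples of a line was at 40, the deposited ratios keep 40 as a value. The values computed here from Ct differed from the deposited log2 levels by at most 0.00164 and from the deposited log2 fold changes of miRNAs by at most 0.00719. No data set was left out, and 0 sample columns were unmapped.

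An assay counted as detected at a Ct of 35 or below. The log2 change is minus the difference of control-normalized Ct, treated minus untreated, and was computed for miRNAs detected in both samples of a line. With 1 sample per group it has no test, and miRNAs were counted at 2-fold. The common response used limma 3.58.1 in R 4.3.3 with the line as a block, on the 44 miRNAs detected in all 4 samples, with a 2-sided test and Benjamini-Hochberg adjustment at 0.05. The block follows from the design, since both samples of a pair come from 1 line. Nothing says that the samples came from more than 1 culture, and p-values measure the spread between these lines only. limma estimated 1 variance for all miRNAs here, so each has the same SE. The test was tried on 50 simulated data sets per setting, built from the real control means with a noise SD of 0.3 cycle and 10 changed miRNAs, and after the results were seen also with a noise SD of 0.58 cycle. Without any change, 2 of 50 sets of whole-cycle readings held a false call at the lower noise and 0 of 50 at the higher. The control means were taken as free of error, so false calls from an error shared by all miRNAs of a line were not simulated.

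Gained and lost assays passed the limit of 35 in 1 sample of a line only, and their folds are bounds, with the undetected well set at 35. The number shared by both lines was set beside the product of the list sizes and tested by Fisher's exact test. A list's median was ranked among 10000 random lists of its size, matched on level in 3 bins, where at least 3 members were detected. Lists, tests, the naming rule and the alternatives first listed were fixed before the data were examined. The rule names miRNAs at least 2-fold changed alike in both lines, assays gained or lost in both, the 5 largest changes each way per line, up to 4 members of each list with the largest changes, those past the adjusted threshold, both arms of miR-155, and the control assays.

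Alternatives replaced the 3 controls by the global mean (mean Ct of miRNAs detected in all 4 samples, per card), by U6, RNU44 or RNU48 alone, or by RNU44 and RNU48 together, moved the detection limit to 32 or 38, raised the threshold to 4-fold or 1.5 on the log2 scale, centred each card, took the deposited fold changes, left out the block, added an intensity trend, or drew reading errors of up to 0.5 cycle 1000 times. Of the 753 miRNA assays, 626 matched a miRNA gene of RefSeq on GRCh38.p14 by name, which was used for host genes only. Assay names are those of the cards and can be old. Precision is limited by the reading step and by the single sample per group. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.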

Results

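Mature microRNAs (miRNAs), the short RNAs that repress messenger RNAs, were measured by stem-loop quantitative PCR in JEKO-1 and MINO, 2 established human lines of mantle cell lymphoma, a cancer of mature B cells. Each line was profiled untreated and after 5 days in 1.5 µM 5-aza-2'-deoxycytidine (5-azadC), a nucleoside that is built into DNA and traps DNA methyltransferases. The 4 groups hold 1 sample each, so no value within a line has a replicate, and the 2 lines are the sole replication of the treatment. Every sample was read on 2 cards, A and B, with 753 miRNA assays together. The unit is the threshold cycle (Ct), in which a later cycle means less template, and wells without amplification are listed at 40.

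Untreated JEKO-1 had 102 miRNA assays detected at a Ct of 35 or below, and 77 were detected after 5-azadC. MINO had 74 untreated and 59 after 5-azadC. The numbers of assays below 40 were 144 and 134 in JEKO-1 and 116 and 100 in MINO, while 558 assays stood at 40 in all 4 samples. The plant and fly assays that serve as negative controls were at 40 in 12 of 12 wells. Of 494 miRNA readings below 40, 99.2% lay within 0.1 of a whole cycle, so changes come in steps of about 1 on the log2 scale. That reading step alone gives a log2 change an SD of 0.451, if each step stands for a uniform spread over 1 cycle. The same control assay read on both cards of a sample differed with a pooled SD of 0.705 Ct over 12 pairs.

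**Figure D1:**
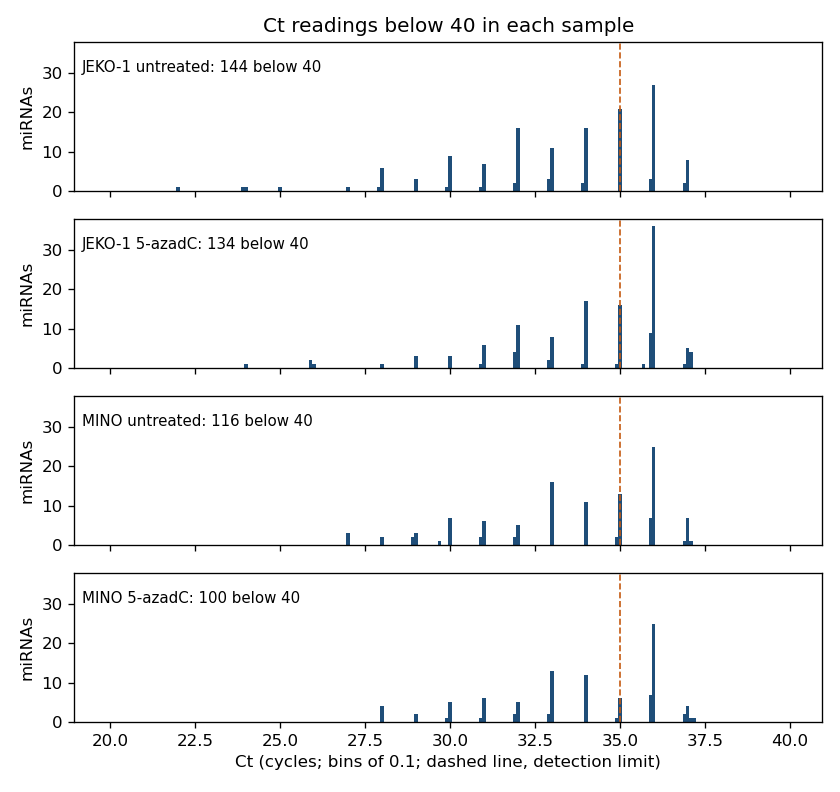
Histograms of the Ct readings below 40 (horizontal axis, cycles; vertical axis, number of miRNAs per bin of 0.1 cycle) in each of the 4 samples, with the detection limit of 35 as a dashed line. The readings stand in narrow columns near whole cycles, and 139 of them lie within 0.1 of 36, above the limit.

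The first comparison asked which miRNAs changed with the demethylating drug in JEKO-1. Among 68 miRNAs detected in both of its samples, 23 were at least 2-fold higher and 5 at least 2-fold lower after 5-azadC. The largest values belonged to miR-181a, a regulator of lymphocyte receptor signalling (log2 change 2.36, 5.14-fold), let-7d of the let-7 family (2.35, 5.10-fold), miR-532 (2.33), miR-29a, which targets de novo DNA methyltransferases (2.32), and miR-128a (2.31). All 5 had the same whole cycle in both samples (miR-181a at a Ct of 32.01 and 31.95), so their rise is the control delay of 2.30 cycles on card A, and with the global mean they were at 1.61 to 1.66. Of the 23 higher miRNAs, 2 came at an earlier cycle after treatment, 8 at the same and 13 at a later one. The lowest were miR-339-5p (log2 change -1.75), miR-1274A (-1.07), miR-20a# (-1.06), rno-miR-7# (-1.05) and miR-1274B (-1.05), where # marks the passenger arm of a hairpin. On card A, 20 of 49 miRNAs were at least 2-fold higher and 1 lower, and on card B 3 of 19 were higher and 4 lower. At least 4-fold, 7 were higher and 0 lower. The split of 23 against 5 became 9 against 8 with the global mean as reference and 11 against 8 with each card centred on its own median.

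In MINO, 8 of 55 miRNAs were at least 2-fold higher and 3 at least 2-fold lower after 5-azadC. The largest values were those of miR-200c, best known from epithelial cells (log2 change 2.44, 5.42-fold), let-7a (2.42, 5.37-fold), miR-345 (1.44), miR-146b, a brake on NF-κB signalling (1.42), and miR-1233 (1.09). The lowest were the hypoxia-inducible miR-210 (-1.58), miR-339-5p (-1.56) and miR-92a (-1.55), with miR-30b (-0.61) and miR-30c (-0.60) next and within 2-fold. Card A gave 4 higher and 3 lower of 46, and card B 4 higher and 0 lower of 9. The 4 on card B had the same whole cycle in both samples and passed the 2-fold limit through the controls, which came 1.02 cycles later in the treated sample. The split of 8 against 3 was 4 against 3 with the global mean, 25 against 0 with U6 alone, 7 against 21 with RNU48 alone, 8 against 11 with RNU44 and RNU48 without U6, and 11 against 2 with centred cards.

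The endogenous controls differed between treated and untreated samples themselves. In JEKO-1, the mean of U6, RNU44 and RNU48 came 2.30 cycles later after 5-azadC on card A and 0.949 later on card B. In MINO, the corresponding delays were 0.428 and 1.02 cycles. On card A of MINO, U6 was 1.26 cycles later while RNU44 and RNU48 moved by 0.0365 and -0.0096 cycles. The median log2 change in JEKO-1 was 0.31 with the 3 controls, 0.86 with U6 alone, 0.04 with RNU44 alone, 0.03 with RNU48 alone and -0.32 with the global mean. In MINO these medians were 0.01, 0.27, -0.01, -0.02 and -0.34, and the changes of named miRNAs are to be read relative to them.

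Across both lines, 44 miRNAs detected in all 4 samples were tested for a common response. The lowest unadjusted p belonged to miR-339-5p, at a mean log2 change of -1.65 ± 0.65 (SE), lower in 2 of 2 lines, with an adjusted p of 0.313 by limma. Mean log2 changes of miR-181a (1.41), miR-29a (1.37), miR-21, which is abundant in many lymphomas (1.37), miR-532 (1.37) and miR-345 (1.35) had the same SE and an adjusted p of 0.313 by limma. Of these, miR-345 was at least 2-fold higher in both lines. The other 4 had the same whole cycle in both samples of either line, so their values follow the card A controls: 2.29 to 2.36 in JEKO-1, where these came 2.30 cycles later, and 0.41 to 0.45 in MINO, where they came 0.428 later. No miRNA passed the adjusted threshold of 0.05 (0 of 44 by limma), and 6 had an unadjusted p under 0.05. With U6 as the sole control, limma called 5 miRNAs, namely miR-181a, miR-345, miR-29a, miR-21 and miR-532, all higher and each at an adjusted p of 0.00826. In simulated whole-cycle readings of the same 44 miRNAs with a noise SD of 0.58 cycle, which gives the residual SD of 0.648 seen in the real fit, this test recovered 2.4% of changes of 1 on the log2 scale, 19.6% of changes of 2 and 87.8% of changes of 4. With a noise SD of 0.3 cycle these shares were 16.2%, 80% and 98.8%. The simulation drew noise for each miRNA on its own and took the control means as free of error. An error shared by all miRNAs of a line, as from the controls, was left out, so these shares cannot describe its effect.

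Only miR-345 was at least 2-fold higher in both lines (log2 change 1.27 in JEKO-1 and 1.44 in MINO), and only miR-339-5p at least 2-fold lower in both (-1.75 and -1.56). In JEKO-1, miR-345 was read 1.03 cycles later after treatment and fell under 2-fold with RNU44 alone (0.99), RNU48 alone (0.98), both (0.99) and the global mean (0.56), while miR-339-5p fell under 2-fold in MINO with U6 alone (-0.73). The cluster member miR-92a went opposite ways, at 1.30 in JEKO-1 and -1.55 in MINO, as did miR-1274B, at -1.05 and 1.05. Across these miRNAs, which are not independent replicates, the changes of the lines had a Pearson correlation of 0.17 and a Spearman correlation of -0.01. The correlation was 0.28 on card A (37 miRNAs) and 0.06 on card B (7 miRNAs). Between the lines, the log2 change of 1 miRNA had an SD of 0.76 once each line's mean change was subtracted.

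**Figure D2:**
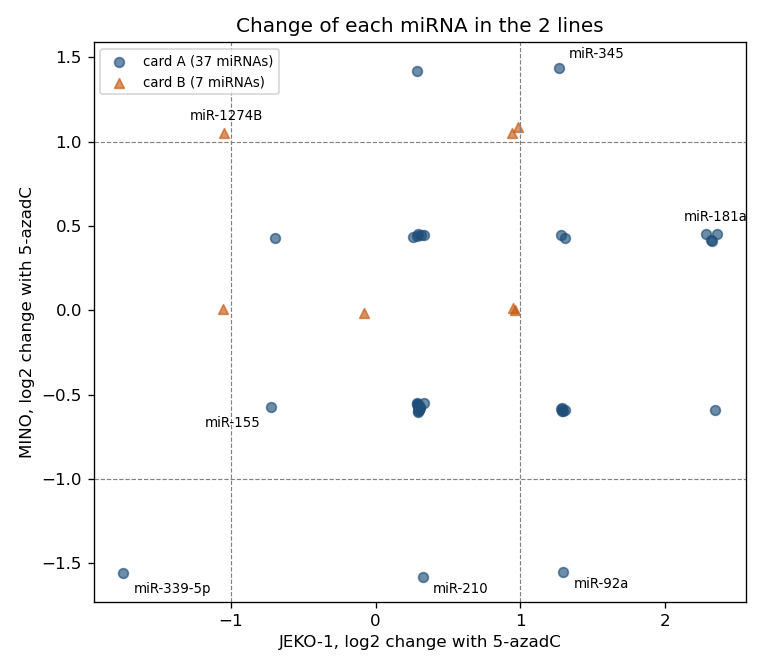
Log2 change with 5-azadC in JEKO-1 (horizontal axis) and in MINO (vertical axis) for the 44 miRNAs detected in all 4 samples, with circles for card A, triangles for card B and dashed lines at 2-fold. Points gather in clumps about 1 log2 unit apart, and only miR-345 and miR-339-5p lie beyond 2-fold in the same direction in both lines with the 3 controls as reference.

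miR-155, an oncogenic miRNA of B cells carried by the MIR155HG transcript, had log2 changes of -0.72 in JEKO-1 and -0.58 in MINO, and a mean of -0.65 with an adjusted p of 0.909 by limma, lower in 2 of 2 lines. That mean was 0.04 with U6 alone, -0.89 with the global mean, -0.98 with RNU44 alone, -1.01 with RNU48 alone and -0.996 with both. Its passenger arm miR-155# was at 40 in both JEKO-1 samples and in untreated MINO, and was read at a Ct of 35.98 in treated MINO, above the detection limit. The authors' deposited table lists a fold change of 32.9 for it in MINO, computed with the well at 40 as a value. Of the deposited fold changes, 58 of 168 in JEKO-1 and 50 of 133 in MINO rest on 1 reading at 40 in this way.

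More assays were lost than gained. In JEKO-1, 9 assays passed the detection limit with treatment alone and 34 without it alone, and in MINO 4 and 19. Among the gained assays, miR-152, a regulator of DNA methyltransferase 1, was at least 5.03-fold higher and miR-381 of the imprinted DLK1-DIO3 cluster at least 5.01-fold higher in treated JEKO-1, and in treated MINO miR-30a-5p was at least 4.18-fold and miR-664 at least 4.16-fold higher. Among the lost, miR-663B was at least 4.12-fold lower in JEKO-1 and the muscle miRNA miR-133a at least 28.6-fold lower in MINO. These 6 were picked after their values were seen, for their large bounds. miR-152 and miR-381 were both read at 34.97, just inside the limit, and their bounds come from the later controls on card A. The other line went the opposite way for miR-152, from a Ct of 35.96 to 40 in MINO, above the limit. It did so too for miR-30a-5p, which was lost in JEKO-1 (log2 change -1.06). By contrast, miR-664 was also higher in JEKO-1 (1.94), and miR-381 in MINO (1.41), with both readings above the limit. Both MINO samples were at 40 for miR-663B, and both JEKO-1 samples for miR-133a. The untreated MINO reading of miR-133a, 29.737, was 1 of 4 readings that lay off the whole cycles. Lost in both lines were miR-130b, miR-26b, miR-454, miR-532-3p, miR-629 and miR-660, 6 assays where independent lists would share 2.95 (Fisher's exact test, 2-sided p = 0.0581), and 0 were gained in both. Against the controls, miR-130b (1.33), miR-660 (1.28), miR-454 (0.30) and miR-26b (0.28) were not lower in JEKO-1. In MINO, miR-454 was at -2.56, miR-26b at -0.59 and miR-660 at -0.56, and miR-130b was at 40 after treatment. The other lost assays, miR-532-3p and miR-629, were at 40 after treatment in both lines. When a loss or gain had to stay 1 cycle clear of the limit after moving readings by the control delay, JEKO-1 kept 3 gained and 3 lost assays, MINO 3 and 4, and no assay was shared.

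The fixed lists gave few coordinated changes. Of 12 B lymphocyte miRNAs measured in all samples, 3 had a mean log2 change of at least 1 (miR-181a, miR-29a and miR-21) and 0 of at most -1, with a list median of 0.36 at the 86.5th percentile of 10000 random lists matched on level. Those 3 were at least 2-fold higher in JEKO-1 alone, through the controls, with 0.45, 0.42 and 0.45 in MINO. Per line, the list median was 0.29 in JEKO-1 (14 members, 13.4th percentile) and 0.42 in MINO (13 members, 79.4th percentile). The list median for the mean of both lines was -0.0049 with RNU48 alone and -0.14 at a detection limit of 32. The let-7 family, tumour suppressors that act on growth genes, had 3 measured members, let-7d, let-7b and let-7e, with a median of 0.87 at the 95.1th percentile, and let-7d itself was at 2.35 in JEKO-1 and -0.59 in MINO. At a detection limit of 38 the median was 0.39. Members outside the main list went both ways: let-7a was at -1.71 in JEKO-1 and 2.42 in MINO, let-7g at 0.29 and -1.56, and let-7f at 0.26 in JEKO-1. The miR-17/miR-92a cluster and its paralogs, growth-promoting miRNAs, had 10 members with a median of -0.12 (40.6th percentile), which was 0.57 with U6 alone, 0.32 in JEKO-1 alone and -0.57 in MINO alone. The list of miRNAs reported as silenced by methylation in blood cancers had 4 members, miR-24, miR-155, miR-193b and miR-342-3p, with a median of 0.11 (52.8th percentile). Over these 4 members, that median was 0.79 in JEKO-1 alone, -0.57 in MINO alone, -0.13 with the global mean and -0.25 with RNU48 alone. Over all 5 members detected in both JEKO-1 samples it was 0.29 (34.3th percentile), against a median of 0.31 for the 68 miRNAs measured there. In JEKO-1, 3 assays of this list were gained (miR-152, miR-27b# and miR-9#) and 5 lost (miR-148a, miR-196b, miR-335, miR-335# and miR-9), and in MINO 0 were gained and 1, miR-26a, was lost. Gains and losses are crossings of the limit in raw Ct. Against the later controls, the lost miR-196b, miR-9 and miR-148a were not lower in JEKO-1, with log2 changes of 1.29, 0.34 and 0.22. The lost miR-335 and miR-335# were at 40 in treated JEKO-1, and miR-26a was at -1.61 in MINO. No list had a call by limma over all 44 miRNAs, and the B lymphocyte list had 3 members with an unadjusted p under 0.05. Adjusted over the list alone, the single measured member of the list that targets DNA methyltransferases, miR-29a, had an adjusted p of 0.0401 by limma, which equals its unadjusted value.

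Loci best known from other tissues were mostly undetected. The imprinted DLK1-DIO3 cluster had 0 of 60 assays detected in untreated JEKO-1 and 1, miR-381, after 5-azadC. The placental C19MC cluster had 0 of 45 assays detected in any sample, the pluripotency clusters 0 of 13 and the X-linked testis clusters 0 of 17. Among 16 assays of p53-induced miRNAs, miR-192 alone was detected, in untreated JEKO-1. Markers of other cell types were sparse: 0 of 13 stromal and 0 of 2 liver assays were detected, of 8 striated muscle assays only miR-133a in untreated MINO, of 10 neural assays miR-9 in untreated and miR-9# in treated JEKO-1, of 12 epithelial assays miR-200c in 3 samples and miR-375 in untreated JEKO-1, and of 9 myeloid and erythroid assays miR-223 in all 4 samples. The neural list also names miR-128, but the name match missed the card's miR-128a, so those 10 assays leave it out. In JEKO-1, miR-128a was detected in both samples, at a Ct of 34.97 untreated and 34.96 treated. In MINO it was at 35.96 untreated and at 40 treated.

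Before treatment, the 2 lines differed in many miRNAs. Of 66 detected in both untreated samples, 29 were at least 2-fold higher in MINO and 15 at least 2-fold higher in JEKO-1. The myeloid miRNA miR-223 was higher in MINO by 3.80 on the log2 scale and miR-342-3p by 3.77, while miR-1274B (-3.72), miR-20a (-2.22) and miR-19a (-2.20) were lower in MINO. miR-222 was read at a Ct of 28.9 in MINO and at 40 in JEKO-1, at least 231-fold higher, and the passenger arm miR-149# was at least 27.1-fold higher in JEKO-1. These examples were picked after their values were seen. The split of 29 against 15 was 40 against 7 with RNU44 and RNU48 without U6, 41 against 6 with RNU44 alone, and 10 against 30 with U6 alone.

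The list of the miR-17/miR-92a cluster stood apart between the untreated lines. Of its 11 members detected in both, 8 were at least 2-fold higher in JEKO-1 and 0 in MINO, with a median of -1.22 (MINO minus JEKO-1, log2) at the 1.16th percentile of random lists. The 6 hairpins of the cluster lie within 1 host transcript, MIR17HG, in RefSeq on GRCh38.p14. Members that share a transcript or a near-identical sequence are not independent, whereas the random lists draw single miRNAs. The percentile can therefore overstate how unusual the list is. Relative to the other miRNAs, the list median differed by -2.996 to -2.04 on the log2 scale under the references tried, whereas its own median was -0.03 with RNU44 alone. Each reference moves a whole card, and 10 of the 11 members are on card A, so the references could change that distance little.

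**Figure D3:**
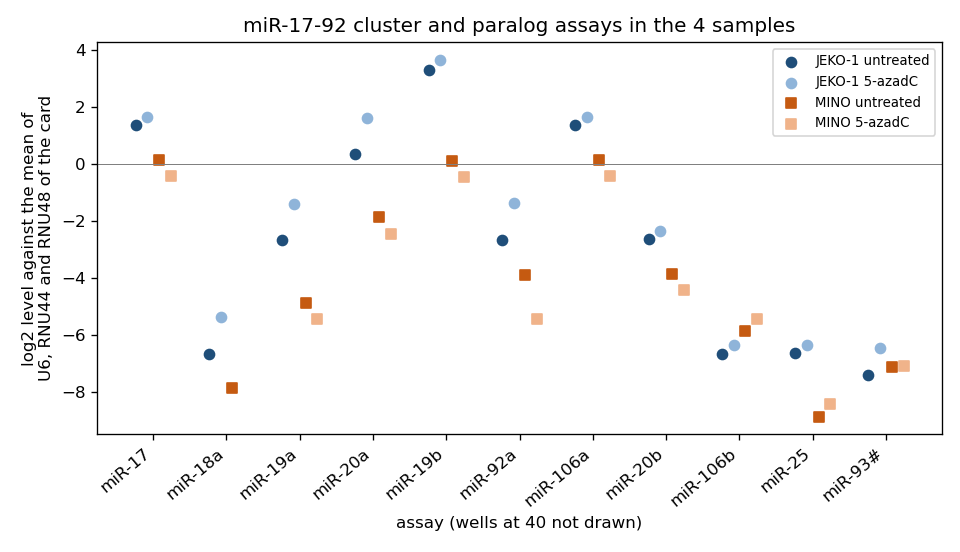
Log2 level (vertical axis, against the mean of U6, RNU44 and RNU48 on the same card) of miR-17/miR-92a cluster and paralog assays (horizontal axis) in the 4 samples, 1 point per sample, with wells at 40 left out. Dark blue circles of untreated JEKO-1 lie above dark orange squares of untreated MINO for most assays with these controls, while miR-106b and miR-93# are among those higher in MINO.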

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

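The tests in this part were chosen after the results were seen, while the limit of 38, the single controls and the global mean were planned settings. Opposite responses of the lines were found for miR-92a, whose log2 change was 2.85 higher in JEKO-1 than in MINO, and for miR-1274B, where JEKO-1 minus MINO was -2.10. Both were at least 2-fold changed in each line with the 3 controls, and the difference was not tested, since each group has 1 sample. The raw Ct of miR-92a was later after treatment in both lines, by 0.999 cycles in JEKO-1 and 1.98 in MINO, so the opposite signs arise against the controls. The signs stayed opposite under every reference. The change in JEKO-1 was 0.59 with the global mean and that in MINO -0.72 with U6 alone, while both stayed at least 2-fold with RNU44 alone (1.02 and -1.94), RNU48 alone (1.01 and -1.99) and both (1.02 and -1.97). In MINO, miR-1274B kept its whole cycle, so its 1.05 is the delay of the card B controls, and it was 0.59 with the global mean.

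Above the detection limit, 3 miRNAs were read in both treated samples and stood at 40 in both untreated ones. They were miR-34a, a p53-induced tumour suppressor often silenced by promoter methylation, at a Ct of 36.99 in JEKO-1 and 35.97 in MINO, miR-328 at 35.96 and 35.99, and miR-338-5P at 36.99 and 37.21. At a limit of 38 they were 3 assays gained in both lines, where independent lists would share 0.429 (Fisher's exact test, 2-sided p = 0.00704). Of the 588 assays in that comparison, 558 stood at 40 in all 4 samples. Counting assays that never amplified makes any overlap look large, so neither value can measure a shared response. Since 5 assays were lost in both lines at the same limit where 1.6 would be shared (Fisher's exact test, 2-sided p = 0.00739), sharing was not particular to gains. These readings lie at the latest cycles recorded, with the highest reading below 40 at 37.2.

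Fewer assays were detected after 5-azadC in both lines. Moving each untreated reading by the control delay of its card predicted 121 treated detections over both lines and cards, against 136 observed, so a later threshold crossing of whole cards may account for the loss. By card, 40 were predicted and 51 observed on card A of JEKO-1, and 23 and 26 on its card B. In MINO these were 49 and 47 on card A, and 9 and 12 on card B. Whether less RNA, weaker reverse transcription or a lower content of small RNA delayed the cards was not tested. An effect of the drug on single miRNAs stays open for the 7 lost assays that remained after the correction, 3 in JEKO-1 and 4 in MINO. It stays open for the others too, since the correction drops assays read near the limit whatever their change. In JEKO-1, miR-197 went from a Ct of 32.02 to 40 and let-7a had a log2 change of -1.71, and neither is among the 7.

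JEKO-1 had 41.2% of its miRNAs changed at least 2-fold and MINO 20%. With reading errors drawn, the ratio of these shares had a median of 1.56 and a 2.5th percentile of 1.01. The draws centre on the observed whole-cycle readings and control delays, so they cannot exclude reading steps near the limit as the cause. For example, miR-20a on card A was read 1 whole cycle later in both lines, which gave 1.28 in JEKO-1 and -0.58 in MINO. The choice of control may account for the difference, since the ratio was 0.809 with RNU48 alone and 0.874 with U6 alone, against 2.10 with RNU44 alone. A stronger response of JEKO-1 stays untested.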

How the results depend on the processing

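The centring of cards, the limits 32 and 38, the 4-fold threshold, the deposited fold changes, the 2-cycle margin, the block, the trend, the global mean and the single controls were planned, except single controls for the untreated lines. RNU44 with RNU48, the 1.5 threshold, reading errors, the shift correction, the untreated lines without card B and leave-one-out of lists were chosen after seeing the data. Where a value moved, the cause was not tested unless stated.

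In JEKO-1, higher and lower counts of 23 and 5 were 9 and 8 with the global mean, 10 and 2 at a limit of 32, 41 and 10 at 38, 7 and 0 at 4-fold, 9 and 1 at 1.5, 65 and 41 in the deposited fold changes, which include wells at 40, and 11 and 8 with centred cards. With RNU48 alone 3 were lower. In MINO, 8 and 3 became 1 and 1 at 32, 15 and 10 at 38, 2 and 0 at 4-fold, and 32 and 43 in the deposited fold changes. Higher counts were 4 with the global mean, 25 with U6 alone and 2 at 1.5. Lower counts were 0 with U6 alone, 21 with RNU48 alone, 11 with RNU44 and RNU48, and 6 with reading errors. Fewer or more miRNAs are tested at 32 and 38 by construction.

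By limma, 0 calls became 5 with U6 alone and stayed 0 under the other 8 settings, where the smallest adjusted p ranged from 0.138 to 0.978. Without the replicate block it was 0.978 with 0 unadjusted p under 0.05. Leaving out a line leaves no test, and 12 of 26 named means then moved by more than 0.76, the SD between lines with each line's mean change subtracted. Of 20 log2 changes named for 1 line, 15 moved by more than the reading SD of 0.451 with U6 alone and 7 with the global mean. None of at least 2-fold changed sign, while miR-30b and miR-30c in MINO became 0.22 and 0.23 with U6 alone. A change of reference moves all miRNAs on a card of a line by 1 value. The counts of 15 and 7 therefore show which cards moved and nothing about single miRNAs, and the 15 are those on card A.

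The 2 miRNAs changed alike were 1 with the global mean, 7 with U6 alone, 1 with RNU44 alone, 4 with RNU48 alone, 0 at 32, 6 at 38, 0 at 4-fold and 1 at 1.5. The Pearson correlation of 0.17 stayed within its 95% interval of -0.13 to 0.45 under each setting run. That interval takes miRNAs as independent, which they are not. Each reference takes 1 value off a whole card, and 37 of the 44 miRNAs are on card A. The references could therefore move the correlation little.

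At a limit of 32, JEKO-1 gained 1 and lost 15, MINO gained 0 and lost 7, and 2 were lost in both. At 38, JEKO-1 gained 24, MINO gained 17 and lost 33, and 3 were gained in both. With the margin of 2 cycles JEKO-1 lost 19, MINO gained 2, and 2 were lost in both. With the shift-corrected limit JEKO-1 gained 3 and lost 3, MINO lost 4, and 0 were lost in both.

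For the untreated lines, counts higher in JEKO-1 were 7 with RNU44 and RNU48, 6 with RNU44 alone and 30 with U6 alone, which left 10 higher in MINO. The miR-17/miR-92a cluster list median between them was -1.93 with the global mean, -0.52 with RNU44 and RNU48, -2.62 with U6 alone and -0.031 with RNU44 alone.

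With U6 alone the response medians were 0.57 for the miR-17/miR-92a cluster list, 1.56 for let-7 and 1.05 for the B lymphocyte list. The latter was 0.11 with the global mean, 0.024 with RNU44 alone, -0.0049 with RNU48 alone, 0.0093 with both and -0.14 at 32. Leaving out a line cannot move a list by more than its SD of 2 lines, so those values decide nothing.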

Other observations

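The tests in this part were chosen after the results were seen. The passenger arms of the miR-17/miR-92a hairpins are all on card B. In untreated JEKO-1, miR-20a# was read at a Ct of 31.96, miR-92a-1# at 32.94, miR-19b-1# at 33.98, miR-17# at 33.997 and miR-18a# at 35.96. In untreated MINO, miR-20a# was read at 35.95 and the other 4 were at 40. From the paralog cluster inside MCM7, miR-106b came at 31.97 in JEKO-1 and 32.97 in MINO and miR-93# at 32.96 in both lines, mmu-miR-93 at 30.96 and 31.96, miR-25 at 31.95 and 35.97, miR-25# at 33.96 and 40, and miR-106b# at 36.02 and 40.

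The higher level of the miR-17/miR-92a cluster of untreated JEKO-1 was weighed against technical explanations. On card A, the raw Ct of the list differed by 3.01 cycles (10 miRNAs) and that of the other 44 miRNAs by 0.0103, a gap of 3.002 cycles. A MINO card A that was weaker as a whole would delay both alike, so it cannot by itself give this gap. A reference takes 1 value off a whole card, so the gap restates the list's distance of -3.002 on card A after normalization. It is therefore no separate test. Cross-detection of near-identical paralogs stays open. Of the 5 passenger arms, which differ in sequence from the paralogs and were all below 40 in JEKO-1, 4 were at 40 in MINO, but so were 23 of 46 other card B miRNAs (Fisher's exact test, 2-sided p = 0.354). Also open is a difference between the lines in the copy number or transcription of the cluster, which was not tested, and whether it would be limited to MIR17HG. In raw Ct, 5 of the 6 MCM7 assays were also later in MINO or at 40 there. Against the controls, miR-106b (0.79), mmu-miR-93 (0.80) and miR-93# (0.29) were higher in MINO on the log2 scale. The others were lower there, with miR-25 at -2.23 and miR-25# and miR-106b# at 40. Each line has 1 untreated sample.

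A further hypothesis was that miRNAs of the same host gene change alike with 5-azadC. Within host genes, log2 changes differed by 0.49 on average in JEKO-1 (17 pairs) and by 0.21 in MINO (5 pairs), at the 2.12th and 3.68th percentiles of 10000 shuffles within cards. Without MIR17HG, which gave 9 and 3 of these pairs, the mean differences were 0.41 in JEKO-1 (8 pairs, shuffled mean 0.98) and 0.52 in MINO (2 pairs, shuffled mean 0.87), at percentiles of 5.98 and 38.7. The pairs left are too few to decide.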
